A study of Mus musculus with 25 samples.

How the data were processed

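Neutrophils sorted from mouse lung were sequenced in 25 libraries of 2 experiments. Per the labels and protocol text, mice were 8 to 10 weeks old. Those of the LPS groups and of the whole second experiment inhaled nebulised LPS at 1 mg/ml, and control animals had no LPS dose given. An anti-Ly6G antibody was injected 2 min before the end to mark neutrophils inside vessels. Perfused lungs were digested with collagenase for 45 min before sorting. RNA had an integrity number above 8 and was made into strand-specific poly(A) libraries. The submitters' processing notes named cutadapt, STAR and featureCounts against mm10, and edgeR for the first experiment, with versions not given in the sources used here.

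The deposited count tables, 1 per experiment, held raw counts per gene that the authors made from aligned reads, and all tests started from these counts. The deposited log2 table of the first experiment held values that the authors normalized to CPM and corrected, with the 3 batch means equal for each gene and the correction method not stated. The deposited signal table of the second experiment held counts that the authors divided by 1 factor per library, which is not plain CPM. Gene symbols came from that table, in which 38872 of 39056 identifiers were in GENCODE M21. Positions are 1-based and refer to mm10.

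Samples were grouped as the labels give them. The first experiment had control vascular, LPS vascular and LPS transmigrated neutrophils, each in batches 1 to 3. The second had transmigrated and non-transmigrated neutrophils of 7 animals labelled Piezo1-KO and 1 WT animal. P-values measure the spread between samples as the labels give them. The WT groups had 1 library each, so the fit pooled the spread and no replicate check was possible for them.

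Differential expression was tested in R 4.3.3 with edgeR 4.0.16 (TMM normalization, filterByExpr with a minimum count of 10 and a minimum total of 15, quasi-likelihood F tests, two-sided, Benjamini-Hochberg adjusted p under 0.05). All 9 libraries of the first experiment were fitted with the batch as a block. The 14 Piezo1-KO libraries were fitted with the day as a factor, the 16 libraries of the second experiment by group means for genotype, and each location alone for the day. The difference between experiments was fitted on the 6 LPS libraries of the first and the 14 Piezo1-KO libraries of the second experiment with batch and animal as blocks, and the difference of the transmigration change between days with the animal as a block. Log2 fold changes of the day are those of day 3 against day 1. CPM are TMM-scaled.

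Genes are named by a rule: the 6 largest log2 fold changes in each direction (4 in the smaller comparisons) among genes past the threshold with a mean log2 CPM of at least 4, a symbol that is not of a predicted gene and the same direction in every batch or animal (for the difference between experiments, no overlap between the changes of batches and animals); up to 4 members per list by adjusted p; and Piezo1, Nox4, Cybb, Hif1a and Ly6g. The comparisons, the rule, the lists and the alternatives were chosen before the data were examined, except for scaling without TMM, the splits by Xist and the paired sign permutation of cell type sums, which were chosen after seeing the data.

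The 32 gene lists, taken from general knowledge, covered NADPH oxidase, primary granule, secondary and tertiary granule, cytokine and chemokine, NF-kB target, interferon-stimulated, glycolysis, hypoxia response, oxidative phosphorylation, adhesion and chemoattractant receptor, pattern recognition and phagocytosis, mechanosensing, YAP target and cytoskeleton, apoptosis and survival, cell cycle, ER stress and heat shock, immediate early, NRF2 antioxidant, cholesterol and lipid and ribosomal protein genes. They also covered markers of alveolar macrophages, monocytes and macrophages, dendritic cells and MHC class II, B cells, T and NK cells, endothelium, alveolar epithelium, airway epithelium, fibroblasts, erythroid cells, platelets, eosinophils, basophils and mast cells, and neutrophils, of which 10 of 18 genes also stood in other lists. All listed genes were matched but 1 erythroid gene. Lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with an inter-gene correlation preset at 0.01, and with an estimated correlation, which left 0 lists past the threshold in any comparison. Members were also counted with p adjusted over the list alone. Cell type markers were summed per library in CPM and compared by exact permutation tests, two-sided, adjusted over 13 cell types, with folds as ratios of geometric means.

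Alternatives were DESeq2 1.42.0, limma voom, DESeq2 size factors, no TMM normalization, 2 other expression filters, a log2 fold change of at least 1, other blocks, subsets of samples, each library, batch, animal or day left out, the authors' tables with limma, and fry for lists. Total counts per library ran from 25627322 to 29315164 in the first and 23022083 to 35572533 in the second experiment, with TMM factors from 0.773 to 1.29 and from 0.546 to 1.37. The tests were tried on simulated data with 200 changed genes, drawn only from genes above a set mean count. Simulated libraries were drawn independently around 1 mean per gene, without batch, animal or day effects. The lone WT library was given the fitted spread, so the rates do not test that assumption. Rates for libraries that correlate within batches or animals were not measured. For LPS vascular against control vascular, with 14174 genes, 60% of 2-fold and 100% of 4-fold changes were recovered with 4.76% false calls. For Piezo1-KO transmigrated against non-transmigrated, with 14568 genes, 93% and 100% were recovered with 2.03% false calls, and for the difference between experiments, with 15389 genes, 75% and 100% with 0.568%. For Piezo1-KO against WT, with 16341 genes, 2% and 48% were recovered with 5.66% false calls, for the day, with 15232 genes, 46% and 100% with 4.58%, and for the day difference of the transmigration change, with 14574 genes, 65% and 98% with 2.4%. In 51 pairs of libraries compared for identity, 0 were identical. No sample was left out of the main comparisons.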

Results

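RNA sequencing of neutrophils sorted from mouse lung covered 25 libraries from 2 experiments. The series title concerns the role of mechanical signals in neutrophils, and the second experiment used animals labelled as knockouts of Piezo1, a mechanically gated cation channel. In the first experiment, neutrophils inside lung vessels were taken from control animals and from animals that inhaled lipopolysaccharide (LPS), and neutrophils that had left the vessels were taken after LPS. Each of these 3 groups had 3 libraries, 1 per batch. In the second experiment, non-transmigrated and transmigrated neutrophils came from 7 animals labelled Piezo1-KO and from 1 animal labelled wild-type (WT). The titles of the WT libraries read Ctrl fl beside that label. Per the protocol text, all animals of the second experiment also inhaled LPS. The labels gave a day for each animal, with the WT animal at day 0 and the Piezo1-KO animals at days 1 (2 animals), 2 (2 animals) and 3 (3 animals), and did not say what the day counted. The labels called all animals male, but the libraries of Piezo1-KO animals 1, 2, 5 and 6 held transcripts of Xist, which female cells express, and hardly any of the Y-linked Ddx3y. Total counts ran from 25627322 to 29315164 per library in the first experiment and from 23022083 to 35572533 in the second, with 16831 to 19617 genes detected per library over both.

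Piezo1 (ENSMUSG00000014444, chromosome 8, 122481698 to 122551329 in mm10) was counted in every library. Its level in the libraries labelled Piezo1-KO was not lower than in the first experiment or in the WT non-transmigrated library. On the TMM scale, 7 of these 14 libraries lay below the WT transmigrated library. That count depends on the scaling, since at raw library size the WT transmigrated library held 56.7 CPM and the WT non-transmigrated library 14.43 CPM. In the first experiment its TMM-scaled level was 27.4 ± 4.37 CPM (SD, n = 3) in control vascular, 27.3 ± 3.14 in LPS vascular and 32.8 ± 5.77 in LPS transmigrated neutrophils. In the second experiment it was 26.4 CPM in the WT non-transmigrated library and 94.2 CPM in the WT transmigrated library. The libraries labelled Piezo1-KO held 82.5 ± 14.5 CPM (SD, n = 7) without transmigration and 115.5 ± 11.8 CPM with it. Single libraries labelled Piezo1-KO ran from 54.4 to 131 CPM, from 1104 to 4933 counts. A count over the whole gene includes exons outside a deleted part, and the labels did not name the deleted part, so these values neither show nor exclude the knockout. Directions drawn below from the Piezo1-KO label rest on that label.

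**Figure D1:**
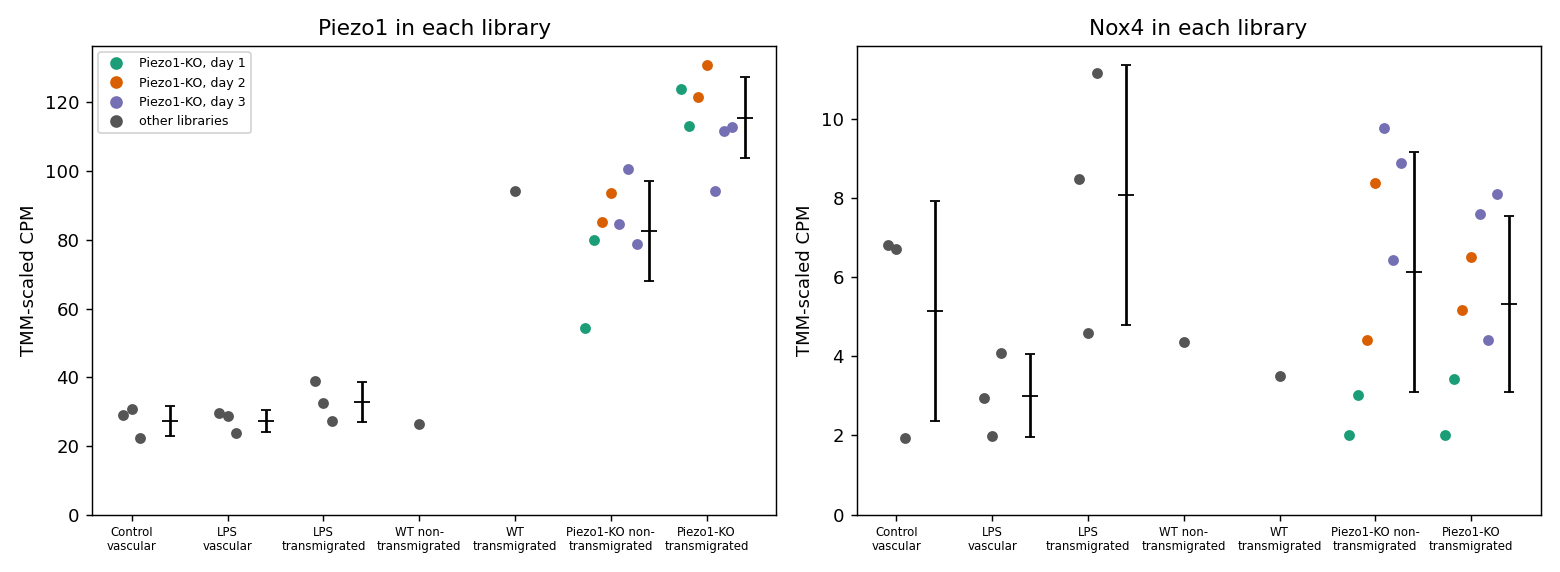
Piezo1 and Nox4 levels in CPM in each library (points, coloured by day in the second experiment) with the group mean and SD (bars). Piezo1 lay between 54.4 and 131 CPM in the libraries labelled Piezo1-KO. It was at 26.4 CPM in the WT non-transmigrated library and at 94.2 CPM in the WT transmigrated library.

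The first principal component of the first experiment carried 38.3% of the variance and ran from control vascular to LPS transmigrated neutrophils, and the second carried 20.7%. Deviations from group means correlated across genes within a batch, with a median r of 0.258 over 9 library pairs, against a median of -0.127 between batches. Genes are not independent replicates. Within a batch, r was 0.535 to 0.663 between LPS vascular and LPS transmigrated libraries. For pairs with a control vascular library it was only 0.0372 to 0.334, so the batch tied mainly the 2 LPS groups. In the second experiment the first component carried 32.7% and parted day 1 and WT libraries from those of days 2 and 3. Deviations from group means in libraries of 1 animal correlated with r from 0.49 to 0.761 across genes, against -0.522 to 0.545 between animals, and centred also on the day with r from 0.286 to 0.601, against -0.442 to 0.302. Centring on means itself pushes correlations between batches or animals below those within them. With 2 animals at a day it makes them mirror images, as with 0.442 and -0.442 at day 1. The values between batches or animals are therefore no independent comparison for those within.

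Vascular neutrophil libraries from LPS-treated and control lungs were compared to see how they differed after inhaled LPS. Transcripts of markers of other cells were present, with alveolar epithelial sums of 3157 CPM in control and 4618 CPM in LPS vascular libraries. A difference in level therefore need not lie within neutrophils, and the cell of origin was not tested. Cxcl10 and other interferon-stimulated genes were higher after LPS. Cxcl10, a chemokine of the interferon response (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889), rose from 41.9 ± 19.8 to 1019 ± 182 CPM (SD, n = 3), a log2 fold change of 4.67 ± 0.38 (SE; edgeR quasi-likelihood adjusted p = 0.000382). Slc26a4, which encodes the anion exchanger pendrin, rose from 1.42 to 54.1 CPM (log2 fold change 5.34 ± 0.22, edgeR adjusted p = 8.81e-06). Ifit1 and Ifit2, antiviral proteins induced by interferon, rose by log2 fold changes of 3.84 and 3.62, and Saa3, an acute phase protein, and Lipg, a lipase, by 3.87 and 3.91. The largest decreases were those of Krt83, a hair keratin (-2.37), Neil1, a DNA glycosylase (-2.22), Jmy (-2.16), Eprs, a tRNA synthetase (-2.15), and the regulators of G protein signalling Rgs2 and Rgs1 (-1.99 for Rgs1). Rgs2 fell from 298.6 to 78.9 CPM (edgeR adjusted p = 0.0111). Piezo1 (-0.00 ± 0.14, edgeR adjusted p = 0.997) and Nox4, an NADPH oxidase that generates hydrogen peroxide (-0.84 ± 0.50, adjusted p = 0.341) did not pass. Nor did Cybb, the catalytic subunit of the phagocyte oxidase (1.00 ± 0.45, edgeR adjusted p = 0.203), Hif1a (0.18 ± 0.37, adjusted p = 0.805) and Ly6g, the neutrophil surface marker (1.08 ± 0.42, adjusted p = 0.144).

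Of the 53 interferon-stimulated genes measured, 42 rose and 0 fell over all genes tested, and 53 rose adjusted over the list alone (median log2 fold change 2.24; camera adjusted p = 1.93e-32, and adjusted p = 0.84 with an estimated correlation). Mx1 (4.07 ± 0.25) and Usp18 (3.54 ± 0.34) were among them. Of 34 cytokine and chemokine genes, 17 rose and 1 fell, and 24 rose and 1 fell adjusted over the list alone (median 1.18; camera adjusted p = 3.44e-13, and adjusted p = 0.84 with an estimated correlation). Ccl20, a chemokine for CCR6-bearing lymphocytes, rose by 6.51 ± 0.26 from 0.164 to 15.4 CPM, and Cxcl5, a neutrophil chemoattractant, by 4.09 ± 0.32. Of 37 genes of pattern recognition and phagocytosis, 12 rose, 14 adjusted over the list alone (camera adjusted p = 1.01e-06), with the inhibitory Fc receptor Fcgr2b at 2.37 ± 0.21 and the LPS receptor Tlr4 at 2.13 ± 0.27. Of 26 NF-kB targets, 5 rose, also 5 adjusted over the list alone (camera adjusted p = 1.24e-06), with Cd40 at 1.62 ± 0.19 and the survival genes Bcl2a1a, Bcl2a1b and Bcl2a1d at 1.61 to 1.90. These last 3 are near-identical copies, so their separate values are uncertain. Both lists had adjusted p = 0.84 with an estimated correlation.

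Of 18 neutrophil markers, 4 rose, 5 adjusted over the list alone (camera adjusted p = 5.33e-05), with the granule collagenase Mmp8 at 2.20 ± 0.30 and the chemokine receptor Cxcr2 at 1.24 ± 0.24. The adhesion and chemoattractant receptor list passed as higher (camera adjusted p = 0.0303), with 2 of 30 members higher and 2 lower, or 3 and 2 adjusted over the list alone. Cd47, the self signal read by phagocytes, and Cxcr2 rose, and the integrin Itgax (-1.03 ± 0.21) and the marrow retention receptor Cxcr4 (-0.95 ± 0.24) fell. The apoptosis and survival list passed as higher (6 of 30 higher, 1 lower, the same numbers adjusted over the list alone, camera adjusted p = 0.0398), but its median of 0.21 turned to -0.10 without TMM normalization. Alveolar epithelial markers also passed as higher (3 of 19 higher, 5 adjusted over the list alone, camera adjusted p = 0.0491), and their median of 0.18 turned to -0.16 without it. Endothelial markers passed as lower (median -0.35, camera adjusted p = 0.0391), with 4 of 19 lower and 1 higher, or 8 and 1 adjusted over the list alone. Each of these 5 lists had adjusted p = 0.84 with an estimated correlation. Summed over each library, the neutrophil markers held 79350 CPM in LPS vascular and 55040 CPM in control vascular neutrophils (1.44-fold, exact permutation p = 0.1, two-sided, the smallest that 3 against 3 libraries allow, 0.65 after adjustment over 13 cell types), and the fibroblast markers 1616 and 2215 CPM (0.741-fold, lower in 3 of 3 batches, exact permutation p = 0.1, also 0.65 adjusted).

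In all, 1474 of 14405 genes passed (987 higher, 487 lower; edgeR quasi-likelihood test with Benjamini-Hochberg adjustment). Without TMM normalization 512 were higher and 672 lower, and the median of all genes moved by -0.31 log2. The count was 89 without batch 1 of all groups, 692 without the batch block, 382, 499 or 745 without LPS vascular replicate 1, 2 or 3, and 673 or 2887 without control vascular replicate 1 or 3.

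Transmigrated and vascular neutrophil libraries of LPS-treated animals were compared to see how they differed. Mmp2 and Cxcl10 were higher in the transmigrated libraries, and Ngp and Ly6g were lower. The libraries also held transcripts of markers of other cells, so a difference in level need not lie within neutrophils. Mmp2, a gelatinase (ENSMUSG00000031740, chromosome 8, 92827291 to 92853420), rose from 20.2 ± 3.08 to 105.4 ± 28.6 CPM (SD, n = 3), a log2 fold change of 2.42 ± 0.31 (SE; edgeR adjusted p = 0.0195). Nbl1, a BMP antagonist (2.06), the collagen VI chains Col6a3 and Col6a2 (both 1.89), Cxcl10 (1.88) and the laminin chain Lama2 (1.85) were the other 5 largest increases. Fibroblast markers summed to 3630 ± 609 CPM in these transmigrated libraries and 1616 ± 112 CPM in the vascular ones (SD, n = 3; 2.23-fold, higher in 3 of 3 batches, exact permutation p = 0.1, the smallest possible). B cell markers summed to means of 1225 ± 837 and 306.3 ± 129 CPM (3.16-fold as a ratio of geometric means, as all folds of sums here, exact permutation p = 0.3) and MHC class II and dendritic cell markers to 1784 ± 371 and 1146 ± 301 CPM (1.58-fold, exact permutation p = 0.1), each higher in 3 of 3 batches. Ngp, a secondary granule protein, fell from 457 to 71.9 CPM (-2.69 ± 0.49, edgeR adjusted p = 0.0226), and Ly6g (ENSMUSG00000022582) from 66.6 to 16.5 CPM (edgeR adjusted p = 0.0274). The kinase Bmx (-2.28), the cadherin Celsr3 (-2.15), the acid phosphatase Acpp (-2.07) and the antimicrobial peptide Camp (-1.98) completed the 6 largest decreases. Nox4 was at 3.01 ± 1.05 CPM in vascular and 8.08 ± 3.29 CPM in transmigrated neutrophils (log2 difference 1.41 ± 0.49, edgeR adjusted p = 0.103, higher in 3 of 3 batches). Piezo1 (0.26 ± 0.14, edgeR adjusted p = 0.27), Cybb (0.50 ± 0.43, adjusted p = 0.491) and Hif1a (-0.19 ± 0.36, adjusted p = 0.779) did not pass.

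Of 16 fibroblast markers, 11 rose and 0 fell, and 15 rose adjusted over the list alone (median 1.43; camera adjusted p = 1.51e-08, and adjusted p = 0.819 with an estimated correlation). Col1a2, a chain of collagen I, rose by 1.77 ± 0.31 and elastin, Eln, by 1.73 ± 0.31. Of 53 interferon-stimulated genes, 19 rose, 35 adjusted over the list alone (median 1.03; camera adjusted p = 1.11e-15, and adjusted p = 0.917 with an estimated correlation), with Cmpk2 at 1.71 ± 0.28 and Ifi203 at 1.03 ± 0.18. Ifit3 (1.59) and Ifit3b (1.62), near-identical copies whose separate values are uncertain, were among them. Of 34 cytokine and chemokine genes, 6 rose, 12 adjusted over the list alone (camera adjusted p = 6.23e-06, and adjusted p = 0.819 with an estimated correlation), including the monocyte chemoattractants Ccl2 (1.38 ± 0.28) and Ccl7. Of 26 NF-kB targets, 3 rose, also 3 adjusted over the list alone, all of them Bcl2a1 copies (camera adjusted p = 0.00577, and adjusted p = 0.917 with an estimated correlation). Monocyte and macrophage markers rose in 5 of 19 cases, 7 adjusted over the list alone, led by the complement genes C1qa (1.91), C1qb (1.72) and C1qc (1.89). The list of ER stress and heat shock genes had 2 of 23 higher, 3 adjusted over the list alone. Among them was the chaperone Hsp90b1 (0.71 ± 0.17, a call lost in 13 of 18 alternatives). The camera adjusted p was 0.00859 for the former and 0.00108 for the latter list, each with adjusted p = 0.819 with an estimated correlation.

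Of 20 secondary and tertiary granule genes, 0 rose and 5 fell, 9 adjusted over the list alone (median -0.77; camera adjusted p = 8.55e-07, and adjusted p = 0.917 with an estimated correlation), with Mmp8 at -1.56 ± 0.30 and the gelatinase Mmp9 at -1.27 ± 0.26. Of 18 neutrophil markers, 5 fell, 7 adjusted over the list alone (camera adjusted p = 0.000515), and their summed level was 0.775-fold that of vascular neutrophils (exact permutation p = 0.2). Of 22 glycolysis genes, 4 fell, or 6 fell and 1 rose adjusted over the list alone (camera adjusted p = 0.000428), with the glucose transporter Slc2a3 at -1.45 ± 0.29 and Gpi1 at -1.16 ± 0.20. Of 40 oxidative phosphorylation genes, Sdhd alone fell (-0.68 ± 0.15) and 0 adjusted over the list alone (median -0.12; camera adjusted p = 0.0303). Each of these last 3 lists had adjusted p = 0.917 with an estimated correlation. The list of NADPH oxidase genes had 0 of 13 members past the threshold and a median of -0.00 (camera adjusted p = 0.851), and the list of mechanosensing, YAP target and cytoskeleton genes had 3 higher and 2 lower of 39 (camera adjusted p = 0.791). The YAP targets Ctgf (1.14 ± 0.22) and Cyr61 (0.81 ± 0.17) rose, and the actin crosslinker Actn1 fell by 0.79.

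In all, 1143 of 14405 genes passed (506 higher, 637 lower; edgeR, Benjamini-Hochberg). The count was 1 without the batch block and 3969 in a blocked fit of these 6 libraries alone. With limma on the authors' corrected log2 table the count was also 1, although the block was kept, so it did not rest on the block alone. It was 0 (edgeR) without LPS transmigrated replicate 1, LPS vascular replicate 1 or LPS vascular replicate 2, where 2018, 2159 and 3234 genes had an unadjusted p under 0.05, and 0 (edgeR; 1455 at an unadjusted p under 0.05) without batch 1 of all groups. It was 39 without LPS vascular replicate 3 and 300 without LPS transmigrated replicate 3.

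LPS transmigrated and control vascular neutrophils differ in both treatment and location, and interferon-stimulated and chemokine genes were higher in the former. Cxcl10 was higher by 6.55 ± 0.42, at 3665 ± 631 CPM (SD, n = 3), Slc26a4 by 5.69 ± 0.22, Ifit1 by 5.42 ± 0.36 and Ifit2 by 5.29 ± 0.39 (SE; edgeR adjusted p = 6.81e-05 or lower). Krt83 (-3.63), Ngp (-3.42), Camp (-3.31) and the mannosidase Man1b1 (-2.70) had the largest decreases. Cybb was higher at 555 than at 157 CPM (edgeR adjusted p = 0.0381, a call lost in 8 of 18 alternatives), whereas Piezo1 (0.26 ± 0.14, adjusted p = 0.203) and Nox4 (0.57 ± 0.49, adjusted p = 0.419) did not pass. All 53 interferon-stimulated genes rose, 53 also adjusted over the list alone (median 3.25), as did 29 of 34 cytokine genes with 1 lower, or 31 and 1 adjusted over the list alone. NF-kB targets rose in 12 of 26 cases, 20 adjusted over the list alone, and pattern recognition genes in 18 of 37 cases, 20 adjusted over the list alone. The camera adjusted p of these 4 lists was 2.5e-31, 3.64e-15, 1.51e-07 and 1.26e-05, and with an estimated correlation adjusted p = 0.79 for cytokines and adjusted p = 0.908 for the others. Immediate early genes (10 of 22 higher and 2 lower, 13 and 3 adjusted over the list alone, camera adjusted p = 0.0228) passed as higher. So did fibroblast markers (7 of 16 higher, 11 adjusted over the list alone, camera adjusted p = 0.000923) and alveolar epithelial markers (6 of 19 higher, also 6 adjusted over the list alone, camera adjusted p = 0.0329). Glycolysis genes passed as lower (6 of 22 lower and 1 higher, 10 and 1 adjusted over the list alone, camera adjusted p = 0.0193). Each of these 4 lists had adjusted p = 0.908 with an estimated correlation. In all, 3938 of 14405 genes passed (2219 higher, 1719 lower; edgeR), or 1155 higher and 2908 lower without TMM normalization, with the median of all genes moved by -0.35 log2. The count was 2255 without the batch block, 2131 in a blocked fit of the 2 groups, 850 without batch 1 of all groups, 1612 without LPS transmigrated replicate 1 and 2205 without control vascular replicate 1.

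**Figure D2:**
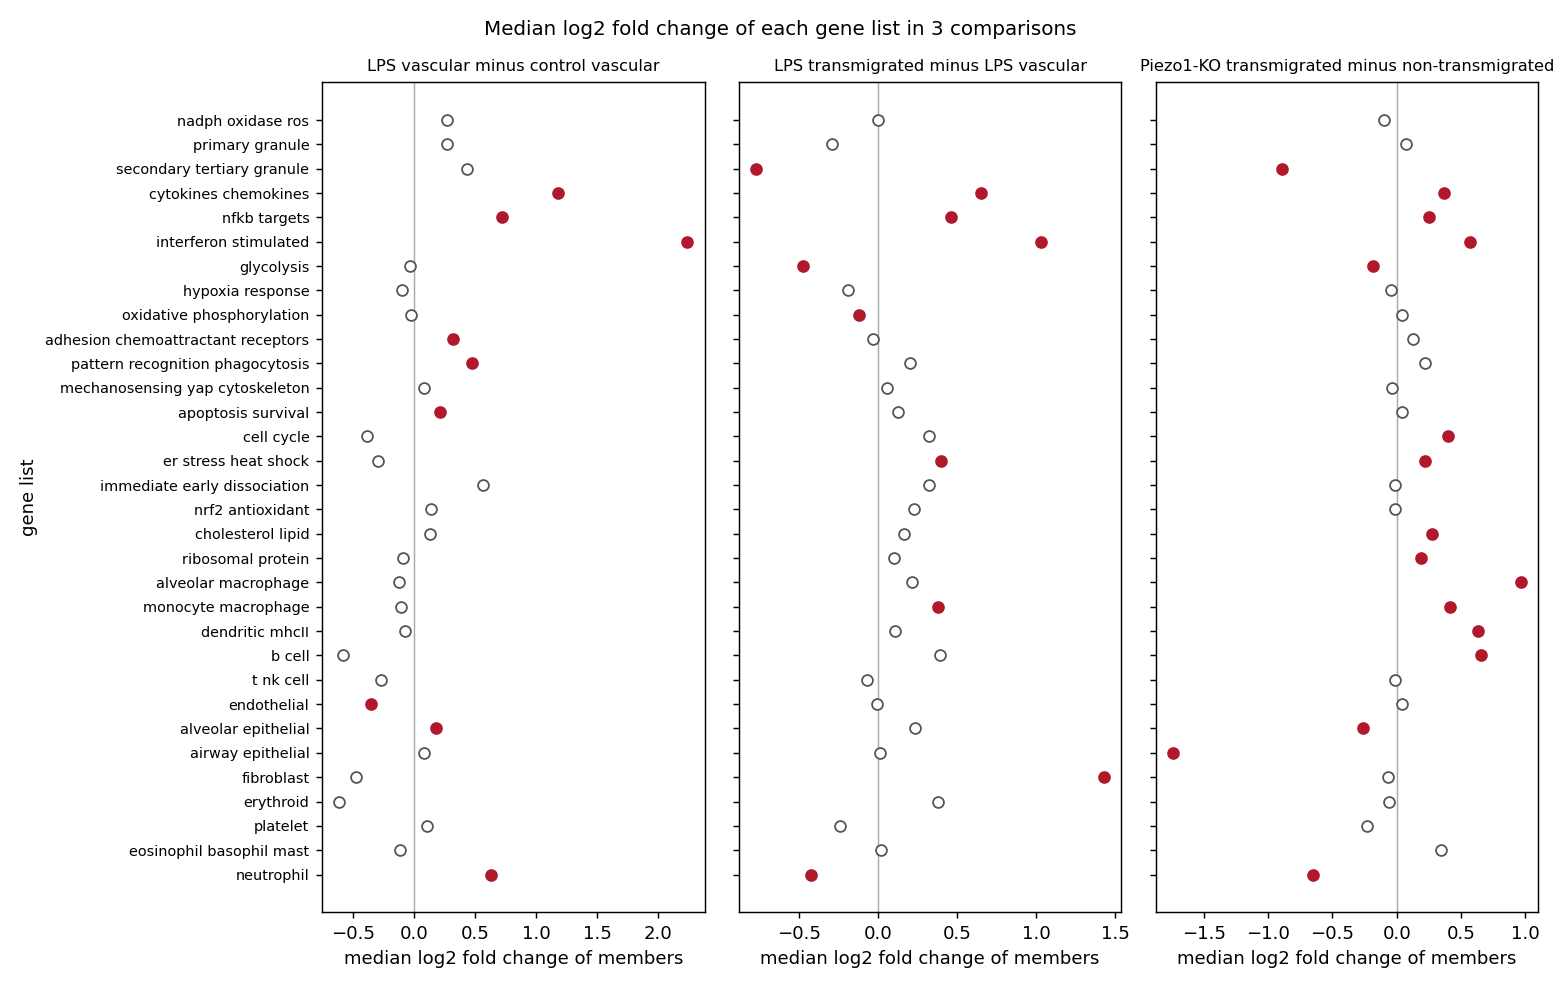
Median log2 fold change of each gene list in LPS vascular against control vascular, LPS transmigrated against LPS vascular and Piezo1-KO transmigrated against non-transmigrated neutrophils. Filled points had a camera adjusted p under 0.05 with the preset correlation, open points did not, and 0 lists passed with an estimated correlation.

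Within the 7 animals labelled Piezo1-KO, transmigrated neutrophils were compared with non-transmigrated neutrophils of the same animals. The main edgeR fit held the day as a factor and not the animal, so its SE and p did not use the pairing. Acpp (ENSMUSG00000032561, chromosome 9, 104288251 to 104337748) fell from 77.4 ± 34.5 to 11.9 ± 3.74 CPM (SD, n = 7), a log2 fold change of -2.70 ± 0.18 (SE; edgeR adjusted p = 1.68e-06), and Bmx from 53.2 to 8.72 CPM (-2.68 ± 0.23). Ngp (-2.58 ± 0.62), Celsr3 (-2.48 ± 0.30), Scgb1a1, the club cell secretoglobin (-2.40 ± 0.27), and the filamin regulator Rflnb (-2.29 ± 0.25) completed the 6 largest decreases. Airway epithelial markers, which include Scgb1a1, summed to 2833 ± 1240 CPM in non-transmigrated and 670 ± 147 CPM in transmigrated libraries (lower in 7 of 7 animals, exact permutation p = 0.000583, two-sided, the smallest possible, 0.00379 after adjustment over 13 cell types). A paired sign permutation within animals, which respects that each animal gave both libraries, had p = 0.0156, its smallest possible, and 0.0254 adjusted. Higher in transmigrated libraries were the short-chain fatty acid receptor Ffar2 (1.51 ± 0.33), the kinase Alpk1, which senses bacterial ADP-heptose (1.44 ± 0.18), and the kinase Tec (1.37 ± 0.24). The immunoglobulin genes Igha (1.48), Jchain (1.44) and Igkc (1.41) were also higher. Whether the immunoglobulin transcripts came from neutrophils was not tested. The B cell markers, among them Igkc, summed to 724 ± 598 CPM in non-transmigrated and 1473 ± 994 CPM in transmigrated libraries (higher in 7 of 7 animals, exact permutation p = 0.0711, 0.185 adjusted, and paired p = 0.0156, 0.0254 adjusted). Immunoglobulin genes form a multigene family, so reads may be shared between them. Piezo1 rose by 0.46 ± 0.11 (edgeR adjusted p = 0.0116), Cybb by 0.75 ± 0.22 (adjusted p = 0.0302), and Ly6g fell by 1.62 (adjusted p = 0.00101), each in 7 of 7 animals. Nox4 (-0.18 ± 0.20, adjusted p = 0.561) and Hif1a (-0.05 ± 0.17, adjusted p = 0.861) did not pass.

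Of 20 secondary and tertiary granule genes, 11 fell, or 13 fell and 2 rose adjusted over the list alone (median -0.89; camera adjusted p = 1.45e-05, and adjusted p = 0.595 with an estimated correlation). Mmp8 was at -1.65 ± 0.17, haptoglobin, Hp, at -1.04 ± 0.15 and S100a8 at -0.93 ± 0.16. Of 18 neutrophil markers, 10 fell, 11 adjusted over the list alone (camera adjusted p = 1.45e-05, and adjusted p = 0.595 with an estimated correlation), and their sum was 0.709-fold that of non-transmigrated libraries (lower in 7 of 7 animals, exact permutation p = 0.114, and paired p = 0.0156, 0.0254 adjusted). Of 12 airway epithelial markers, 11 fell, 12 adjusted over the list alone (camera adjusted p = 1e-08, and adjusted p = 0.595 with an estimated correlation). Of 22 glycolysis genes, 5 fell and 1 rose, the same numbers adjusted over the list alone (camera adjusted p = 0.011, and adjusted p = 0.678 with an estimated correlation), with Slc2a3 at -1.85 ± 0.17. The alveolar epithelial list passed as lower with 2 of 19 lower and 0 adjusted over the list alone (camera adjusted p = 0.0131, and adjusted p = 0.595 with an estimated correlation).

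B cell markers rose in 10 of 15 cases, 11 adjusted over the list alone, and MHC class II and dendritic cell markers in 7 of 14, 9 adjusted over the list alone. Alveolar macrophage markers rose in 9 of 16 with 1 lower, 14 and 2 adjusted over the list alone. The camera adjusted p of these 3 lists was 5.7e-06, 2e-06 and 4.27e-05, each with adjusted p = 0.595 with an estimated correlation. Cd79a rose by 0.74 ± 0.16, the invariant chain Cd74 by 0.64 ± 0.13 and the cytokine Il18 by 0.96 ± 0.18. The summed alveolar macrophage markers were 1.95-fold higher (7 of 7 animals, exact permutation p = 0.00874, 0.0379 adjusted) and the monocyte and macrophage markers 1.27-fold higher (7 of 7 animals, exact permutation p = 0.000583, 0.00379 adjusted). The paired p was 0.0156 for both, and also for the MHC class II (1.60-fold), T and NK cell (1.18-fold) and alveolar epithelial sums (0.836-fold), by exact sign permutation, 0.0254 adjusted. As a list, monocyte and macrophage markers had 4 of 19 higher, 7 adjusted over the list alone (camera adjusted p = 0.000686), and cholesterol and lipid genes 4 of 30 higher and 1 lower, 7 and 1 adjusted over the list alone (camera adjusted p = 0.000128). Both had adjusted p = 0.595 with an estimated correlation, and the cholesterol transporter Abcg1 rose by 0.87 ± 0.17. Interferon-stimulated genes passed as higher with 3 of 53 members higher and 0 adjusted over the list alone (median 0.57; camera adjusted p = 1.45e-05, and adjusted p = 0.807 with an estimated correlation). Of 34 cytokine genes, 8 rose and 2 fell, or 10 and 2 adjusted over the list alone (camera adjusted p = 0.000759, and adjusted p = 0.678 with an estimated correlation), and Ccl20 fell by 1.58. Cell cycle (3 of 31 higher, 1 lower, the same adjusted over the list alone), ER stress and heat shock (2 of 23 higher, 2 lower, 4 and 2 adjusted over the list alone) and ribosomal protein genes (4 of 80 higher, 0 adjusted over the list alone) passed as higher. Their camera adjusted p was 0.000623, 0.031 and 5.57e-09, each with adjusted p = 0.678 with an estimated correlation. Of 26 NF-kB targets, 5 rose and 1 fell, or 7 and 2 adjusted over the list alone (camera adjusted p = 0.0158, and adjusted p = 0.807 with an estimated correlation).

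The lists of NADPH oxidase (camera adjusted p = 0.375), mechanosensing (0.796), hypoxia response (0.775), NRF2 antioxidant (0.367), oxidative phosphorylation (0.306), adhesion receptor (0.165), pattern recognition (0.0992), apoptosis (0.297), immediate early (0.306) and primary granule genes (0.808) did not pass. Nor did the markers of T and NK cells (camera adjusted p = 0.57), endothelium (0.367), fibroblasts (0.708), erythroid cells (0.9), platelets (0.796) and eosinophils, basophils and mast cells (0.515). In all, 2444 of 14655 genes passed (786 higher, 1658 lower; edgeR with the day as a factor), and 4890 passed with the animal as a replicate block (2245 higher, 2645 lower). The count was 1292 without animal 3, 1141 without animal 4, 986 without day 1, 449 without day 2, and 1423 and 917 in the animals without and with Xist transcripts alone.

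**Figure D3:**
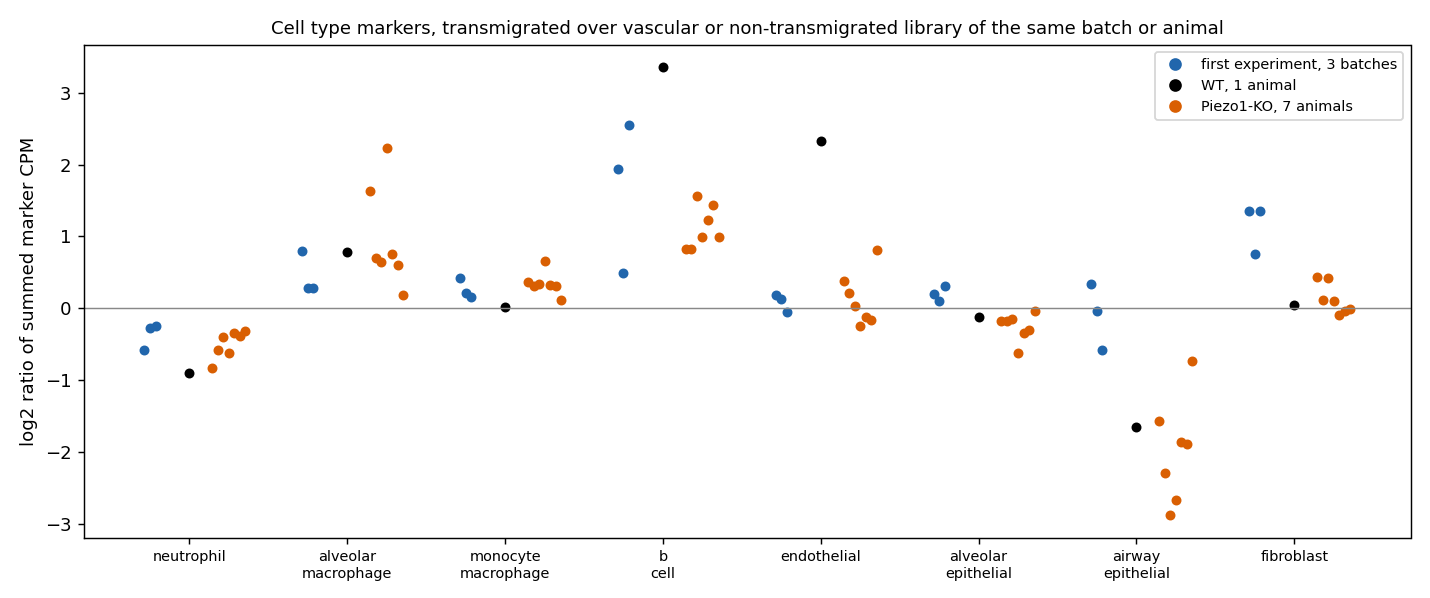
Log2 ratio of summed cell type markers in transmigrated over vascular or non-transmigrated neutrophils, per batch or animal (points). Airway epithelial markers were lower in 7 of 7 animals labelled Piezo1-KO, and fibroblast markers were higher in 3 of 3 batches of the first experiment.

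The change on transmigration was then compared between experiments. It was taken as the change in animals labelled Piezo1-KO minus that in the LPS-treated animals of the first experiment. Both sets of animals had inhaled LPS. Mmp2 changed by 0.03 ± 0.33 (SD, n = 7) in Piezo1-KO animals and by 2.32 ± 0.62 (SD, n = 3) in the first experiment, a difference of -2.34 ± 0.24 (SE; edgeR adjusted p = 0.000168). Nbl1 (-2.08 ± 0.18), Col6a3 (-1.89 ± 0.21), Col6a2 (-1.88 ± 0.20) and the collagen V chain Col5a1 (-1.85 ± 0.16) differed in the same direction, and so did Scgb1a1 (-2.17 ± 0.42). Nox4 changed by -0.14 ± 0.27 in Piezo1-KO animals and by 1.25 ± 0.19 in the first experiment, a difference of -1.59 ± 0.21 (edgeR adjusted p = 0.000524). Among genes whose values in the 7 animals and the 3 batches did not overlap, the largest positive differences were those of the galectin Lgals3 (1.03 ± 0.22), the acetyltransferase Kat6b (0.89 ± 0.20), the ferritin receptor Ncoa4, Tmco3, the septin Sept9 and vimentin, Vim (each 0.87). Tlr7, whose values overlapped, differed by 1.02 ± 0.27 (edgeR adjusted p = 0.0434, a call lost in 10 of 22 alternatives). For Nox4 the values did not overlap. Piezo1 (0.22 ± 0.18, edgeR adjusted p = 0.558), Ly6g (0.30 ± 0.25, adjusted p = 0.55), Cybb (0.34 ± 0.30, adjusted p = 0.585) and Hif1a (0.13 ± 0.14, adjusted p = 0.665) did not pass.

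Of 16 fibroblast markers, 15 had a lower change in Piezo1-KO animals, also 15 adjusted over the list alone (median -1.44; camera adjusted p = 1.73e-15, and adjusted p = 0.639 with an estimated correlation). Of 53 interferon-stimulated genes, 14 did, 26 adjusted over the list alone (median -0.51; camera adjusted p = 9.8e-11, and adjusted p = 0.662 with an estimated correlation), with Ifit2 at -1.15 ± 0.19 and the guanylate-binding protein Gbp5 at -1.03 ± 0.21. Airway epithelial markers (4 of 12 lower, 12 adjusted over the list alone, camera adjusted p = 1.35e-06) and cytokine genes (7 of 34 lower, 10 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.000178) were lower, each with adjusted p = 0.639 with an estimated correlation. Among the cytokines, Ccl20 differed by -1.67 ± 0.27, Lif by -1.25 ± 0.21 and Il6 by -1.07 ± 0.19. Alveolar epithelial (2 of 19 lower, 9 adjusted over the list alone, camera adjusted p = 0.000335) and NRF2 antioxidant genes (3 of 22 lower, or 3 lower and 1 higher adjusted over the list alone, camera adjusted p = 0.0365) also passed as lower, each with adjusted p = 0.662 with an estimated correlation. ER stress genes (0 of 23 past the threshold, camera adjusted p = 0.0172, and adjusted p = 0.639 with an estimated correlation) passed as a lower list. So did NF-kB targets (0 of 26, camera adjusted p = 0.0237) and immediate early genes (1 of 22 lower, camera adjusted p = 0.0425), the latter 2 with adjusted p = 0.756 with an estimated correlation. MHC class II and dendritic cell markers passed as higher with 1 of 14 higher, 4 adjusted over the list alone (camera adjusted p = 0.00214). So did oxidative phosphorylation genes with 0 of 40 (camera adjusted p = 3.17e-05), each with adjusted p = 0.662 with an estimated correlation. Ribosomal protein genes (0 of 81, camera adjusted p = 0.000236) and glycolysis genes (0 of 22, camera adjusted p = 0.0231) passed as higher lists. So did B cell markers (0 of 15, camera adjusted p = 0.0237) and alveolar macrophage markers (0 of 17 higher and 1 lower, camera adjusted p = 0.03). Each had adjusted p = 0.756 with an estimated correlation. In all, 780 of 15771 genes differed (133 higher, 647 lower; edgeR with batch and animal blocks). The experiments were done apart, so genotype and experiment cannot be told apart. Sex may differ as well, since part of the Piezo1-KO animals held Xist transcripts. Of 35 named calls, 34 were kept with the animals with Xist alone and 2 with those without Xist alone. These subsets also differ in number of animals and in day, so what made the calls depend on them was not tested. The edgeR count was 0 without the blocks (1005 genes at an unadjusted p under 0.05), 6 in the animals without Xist transcripts alone, 205 and 327 without batch 1 or 3 of the first experiment and 1243 without Piezo1-KO animal 7.

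Animals labelled Piezo1-KO were compared with the WT animal in each location. The WT library had no replicate and was assumed to vary like the others, so SE and p below rest on the spread of Piezo1-KO libraries and support no difference between genotypes. Without transmigration, the collagen chain Col6a3 was at 34.4 CPM in Piezo1-KO animals and 689.7 CPM in the WT library (log2 difference -4.33 ± 0.40, SE; edgeR adjusted p = 3.27e-05), and with transmigration at 33.5 and 920.4 CPM (-4.78 ± 0.39, edgeR adjusted p = 1.38e-05). The mitotic gene Ckap2l (-2.95 and -3.15) and the Cdk5 activator Cdk5r1 (-3.00 and -2.51) were also lower in both locations. Cd22 (3.71), Mical2 (3.43) and Tjp1 (3.29) were higher and the coagulation factor F13a1 (-3.07) lower without transmigration, and the scavenger receptor Marco (3.55), Slc39a2 (3.13) and Retnla (3.04) higher and the muscarinic receptor Chrm3 (-2.67) lower with it. Without transmigration Piezo1 was at 26.4 CPM in the WT library and 54.4 to 100.5 CPM in those of Piezo1-KO animals (14.43 and 43.32 to 137.7 CPM at raw library size; log2 difference 1.64 ± 0.30, edgeR adjusted p = 0.00334), and it did not pass with transmigration (0.29 ± 0.27, edgeR adjusted p = 0.494). Summed neutrophil markers held 146900 TMM-scaled CPM in the WT non-transmigrated library and 30500 to 78540 CPM in those of Piezo1-KO animals. The TMM factor was 0.5459 in that WT library and 0.7957 to 1.371 in the others, so the size of this gap depends on the scaling. In all, 3784 of 17017 genes passed without transmigration (2074 higher, 1710 lower) and 1347 with it (500 higher, 847 lower; edgeR). For the former count, 1713 were higher and 2215 lower with DESeq2 size factors and 4673 higher and 234 lower without TMM normalization (median of all genes moved by -0.18 and 1.00 log2). In the same comparison 1374 passed with voom, 2244 and 2508 without Piezo1-KO animal 3 or 5, 6043 in animals without Xist transcripts alone and 675 with day 1 alone. The latter count was 2226 with DESeq2, 808 with voom, 155 without TMM normalization (112 higher; median moved by 0.87 log2), 611, 720, 762 and 2381 without Piezo1-KO animal 3, 4, 5 or 7. The WT animal stood alone at its day, so genotype and day cannot be told apart. The genotype difference of the transmigration change passed for 0 of 17017 genes (edgeR; 1827 at an unadjusted p under 0.05, 25 with DESeq2, 0 with voom, 2120 with the animal as a replicate block), and for Piezo1 it was -1.35 ± 0.37 (edgeR adjusted p = 0.268).

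Animals labelled Piezo1-KO were also compared between days, each location alone. Kdr and Tnfsf10 were higher, and Ighm lower, at day 3 than at day 1 in both locations. Kdr, a VEGF receptor of endothelium, was higher by 3.26 without and 2.87 with transmigration, and the TNF family ligand Tnfsf10 by 2.91 and 3.04 (edgeR adjusted p = 0.018 or lower for the test over days). Emp2 (2.85) and the basement membrane collagen Col4a3 (2.83) were higher without transmigration, and Kitl (2.77) and the endothelial gene Ramp2 (2.76) with it. Ighm, the IgM heavy chain, was lower by log2 differences of -2.84 and -3.16. The enzyme Pmvk (-2.18) and Cd300lb (-1.95) were lower without transmigration, and Tlr8 (-1.67) and the leptin receptor Lepr (-1.61) with it, as was the immunoglobulin segment Ighv1-26 (-2.70), whose reads may come from related segments. Endothelial markers summed to 639.8 ± 53.0 CPM at day 1 (SD, n = 2) and 2234 ± 446 CPM at day 3 (SD, n = 3) without transmigration. There, alveolar epithelial markers summed to 2253 and 5961 CPM, B cell markers to 1533 and 353.7 CPM, and neutrophil markers to 77620 and 42500 CPM. TMM factors of these libraries were 0.7957 and 0.8064 at day 1 and 0.959 to 1.371 at day 3, so the size of these differences depends on the scaling. Nox4 passed without transmigration (1.69, edgeR adjusted p = 0.0487, a call lost in 6 of 13 alternatives) beside fibroblast sums of 1560 and 3282 CPM, and not with it (1.36, edgeR adjusted p = 0.152), and Piezo1 passed in neither location (0.36 and -0.10, edgeR adjusted p = 0.461 and 0.716). In all, 1190 of 15505 genes passed without transmigration (760 higher, 430 lower) and 580 of 15426 with it (491 higher, 89 lower; edgeR). Without TMM normalization 2529 and 1061 passed, 94.7% of the former higher against 63.9%, with the median of all genes moved by 0.60 and 0.30 log2. The former count was 4, 3, 594, 406, 561 and 3328 without animal 1, 2, 4, 5, 6 or 7, and the latter 0 (edgeR; 1889 at an unadjusted p under 0.05), 2, 183, 140, 175 and 2338 without animal 1, 2, 3, 4, 5 or 7. The transmigration change itself differed between days for 1 of 14655 genes, Igha (0.90 from day 1 to day 3, edgeR adjusted p = 0.0483), and for 111 genes with DESeq2. The call for Igha was lost in 10 of 14 alternatives.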

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

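The tests of the explanations weighed in this part were chosen only after the results were seen. The difference of the transmigration change between Piezo1-KO animals and the first experiment passed for 780 genes and was flagged as a difference between groups. The gene-wise differences so flagged were Lgals3 (1.03), Kat6b (0.89), Ncoa4 (0.87), Tmco3 (0.87), Sept9 (0.87), Vim (0.87), Mmp2 (-2.34), Scgb1a1 (-2.17), Nbl1 (-2.08), Col6a3 (-1.89), Col6a2 (-1.88), Col5a1 (-1.85) and Nox4 (-1.59). The day difference of the transmigration change was flagged in the same way for 1 gene, Igha.

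Fibroblast genes and Nox4 were higher in transmigrated libraries of the first experiment, Nox4 without passing there, and not in those of Piezo1-KO animals. RNA from lung fibroblasts cannot be judged from the 16 of 16 fibroblast markers with a positive log2 fold change, since these are part of the pattern. Nox4 followed the fibroblast sum over the 7 non-transmigrated Piezo1-KO libraries (Pearson r = 0.977, exact permutation p = 0.000397), but both differed by day, and centred on the day r was 0.928 (exact permutation within days p = 0.0833, 24 permutations), which leaves open whether Nox4 reads came from the same fibroblast RNA. A lower neutrophil share in these transmigrated libraries, with an unchanged mix of the other cells, is ruled out as the whole cause. The endothelial markers had a median of -0.0046 (SD 0.162) while fibroblast markers had 1.43 (SD 0.386). A lower share filled by fibroblasts was not tested. The Piezo1 genotype cannot be judged, because the 1 WT animal, with a fold of 1.03 for the fibroblast sum, is single and the experiments were done apart.

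Libraries of Piezo1-KO animals differed by day. A lower neutrophil share at later days, with an unchanged mix of the other cells, is ruled out as the whole cause. The B cell sum of day 3 was 0.231 times that of day 1 while the endothelial sum was higher. A lower share with a changed mix of the other cells was not tested. Sex of the animals is ruled out as the whole cause, since the lowest endothelial sum of the female day 3 animals without transmigration was 3.42 times the highest of day 1, whose animals were also female, and with transmigration these sums were 2123 and 786.8 CPM. A batch of preparation tied to the day cannot be told from other differences between days, and 0 days hold both genotypes. Apart from sex no biological explanation was tested, since the labels do not say what the day counts.

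Piezo1 in the libraries labelled Piezo1-KO was not lower than in the first experiment or the WT non-transmigrated library. RNA from endothelial cells, which express Piezo1, cannot be ruled out. At day 1 the lowest quotient of Piezo1 over the endothelial sum was 2.03 times the highest of the first experiment. Per 100 CPM of endothelial markers, Piezo1 was at 2.29 to 4.44 CPM in the first experiment. The WT non-transmigrated and transmigrated libraries also lay above that range, at 7.59 and 5.4 CPM. Lying above the first experiment therefore cannot decide the question. Day 1 libraries ran from 9.04 to 15.7 CPM, above both WT libraries, but 1 WT animal gives no spread. At days 2 and 3 the values ran from 3.28 to 6.57 CPM, overlapping the first experiment. Exons outside the deleted part cannot be judged from counts per gene, and Piezo1 was above the WT non-transmigrated library in 14 of 14 libraries.

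Counts of genes past the threshold were set against counts for other splits of the same libraries. For LPS vascular against control vascular, the real split gave 599 genes without a block against at most 0 in the others of 10 splits, and 896 with the block against 0 in 4 splits. For LPS transmigrated against LPS vascular, these were 9 against 1 and 3969 against 0, and for LPS transmigrated against control vascular 2206 against 1 and 2131 against 0. So few splits allow no share under 0.05. For Piezo1-KO transmigrated against non-transmigrated, 2444 stood against at most 390 in 50 drawn splits and 1 in 64 splits that parted every animal, and for the difference between experiments 780 against 0 in 30 drawn splits. In each case 1 split, the real one, reached the real count.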

How the results depend on the processing

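Of 226 counts and levels, 115 stayed within 1.5 times under the alternatives and 111 did not. Of the single genes, lists and cell types, 8019 values kept their side of the threshold, 1492 lost a call and 86 gained one. Values that passed in neither fit counted as kept. Among single genes past the threshold in the main or the alternative fit, 0 turned direction. For the other genes the direction was not checked. The medians of 2 lists that passed for LPS vascular against control vascular turned without TMM normalization. Where no construction is named below, the cause was not tested. A log2 fold change of at least 1, which by construction keeps fewer genes, left 955 (LPS vascular against control vascular), 621 (LPS transmigrated against LPS vascular), 2160 (LPS transmigrated against control vascular), 520 (Piezo1-KO transmigrated against non-transmigrated), 441 (difference between experiments) and 0 (day difference of the transmigration change). Without the replicate block the first 3 counts were 692, 1 and 2255, the difference between experiments 0 and the day difference 0, and with only the 2 groups compared, blocked, the first 3 were 896, 3969 and 2131. With the animal as a replicate block, Piezo1-KO transmigrated against non-transmigrated had 4890 and the genotype difference 2120 genes, and without a day term the former had 996. DESeq2 gave 1839 for LPS transmigrated against LPS vascular, 2226 for Piezo1-KO against WT transmigrated, 25 for the genotype difference, 3244 and 1987 for the day without and with transmigration and 111 for the day difference, and voom gave 1374 and 808 for Piezo1-KO against WT without and with transmigration and 744 for the day without it. Limma on the authors' corrected log2 table, with the batch block kept, gave 1 for LPS transmigrated against LPS vascular. Without TMM normalization counts were 577 for LPS transmigrated against LPS vascular, 155 for Piezo1-KO against WT transmigrated, 2529 and 1061 for the day and 0 for the day difference, whose median moved by -0.37 log2; the median of the genotype difference moved by -0.13 log2, and by 0.10 log2 with DESeq2 size factors. These size factors gave 0 for the day difference. Without an expression filter 1300 genes passed for the difference between experiments, 3661 and 1265 for the day and 470 for the day difference, and with a filter at 1 CPM 0 for the last. Animals without Xist alone gave 1423 for Piezo1-KO transmigrated against non-transmigrated, 6043 for Piezo1-KO against WT non-transmigrated and 6 for the difference between experiments, and animals with Xist alone 917 for the first. Piezo1-KO of day 1 only gave 675 for Piezo1-KO against WT non-transmigrated, 1 for the genotype difference and 459 for the difference between experiments, where days 2 and 3 alone gave 493 and 359. Leaving out single libraries gave 382 to 2887 for LPS vascular against control vascular, 0 to 1091 for LPS transmigrated against LPS vascular and 1612 to 4657 for LPS transmigrated against control vascular. Leaving out whole batches gave 89 and 713 for the first (batches 1 and 2), 0 and 671 for the second (batches 1 and 3) and 850 for the last (batch 1). Leaving out an animal or day gave 1141 to 3643 and 986 and 449 (days 1 and 2) for Piezo1-KO transmigrated against non-transmigrated. Leaving out an animal gave 2244 to 5665 and 611 to 2381 for Piezo1-KO against WT, 568 to 1243 for the difference between experiments (205 and 327 without batch 1 or 3 of the first experiment), 3 to 3328 and 0 to 2338 for the day and 0 to 13 for the day difference. Of the list calls, 0 held with an estimated correlation in each of the 5 comparisons, and fry kept 1, 0, 3, 8 and 5 of the 9, 10, 8, 16 and 15 calls of camera, with 8 kept without the block for the difference between experiments. Piezo1 at raw library size was 32.6 CPM in control vascular, 56.7 in WT transmigrated, 14.43 in WT non-transmigrated and 127.5 in Piezo1-KO transmigrated libraries. Among the genes always reported, calls were lost for Ly6g in 9 of 18 alternatives (LPS transmigrated against LPS vascular) and, in Piezo1-KO transmigrated against non-transmigrated, for Cybb in 6 and Piezo1 in 4 of 22. Among other named genes, calls were lost, for example, for Krt83 and Cxcr4 in 8 of 18 (LPS vascular against control vascular). For LPS transmigrated against LPS vascular they were lost for Mmp2 in 7, Cxcl10 and Ngp in 8, Cyr61 in 10 and Sdhd and Actn1 in 11 of 18. For the difference between experiments they were lost for Vim in 11 and Ncoa4 in 9 of 22. They were also lost for Tjp1 in 8 and Marco in 6 of 15 (against WT) and Ighm in 6 of 13 (day with transmigration). An exact sign permutation within animals, chosen after seeing the data, gave p = 0.0156, its smallest possible, for 8 of 13 cell type sums in Piezo1-KO transmigrated against non-transmigrated libraries, where permutation over libraries gave p under 0.05 for 4. No alternative varied the depth, so what depth limits was not tested.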

Other observations

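Several genes outside the lists that passed also differed after LPS in the vascular neutrophil libraries. Xbp1, a transcription factor of the unfolded protein response, rose by 3.26, the vasodilator peptide Adm by 2.48, the cytokine signalling inhibitor Socs3 by 2.51 and hexokinase Hk2 by 1.76, and Fosb fell by 1.88 (edgeR, adjusted p under the threshold for each). Noxa1 and Noxo1, the activator and organizer of the NADPH oxidase Nox1, rose by 2.35 and 1.84 (calls lost in 8 of 16 and 4 of 18 alternatives), while their list did not pass (camera adjusted p = 0.249).

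In Piezo1-KO animals, transmigrated neutrophils had less Nos2, the inducible nitric oxide synthase (-1.57), and more of the proton channel Hvcn1 (0.86), whose call was lost in 10 of 22 alternatives. G6pdx, which supplies NADPH, fell by 1.01 and the oxygen sensor Egln3 rose by 1.08 (edgeR, adjusted p under the threshold for each).

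In the 1 WT animal, B cell markers summed to 549 CPM in the non-transmigrated and 5623 CPM in the transmigrated library. Endothelial markers summed to 348 and 1746 CPM and airway markers to 871 and 279 CPM. Xist was at 172.5 to 326.1 CPM in both libraries of Piezo1-KO animals 1, 2, 5 and 6, and at 10.35 CPM beside 168.1 CPM of Ddx3y in control vascular replicate 2. Distances of single libraries from their group were tested in 40 groups of values of the 2 Piezo1-KO groups, since the other groups had 3 libraries or fewer, with 0 past the threshold of the Dixon test.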
